A study of Homo sapiens with 8 samples.

How the data were processed

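RNA was measured by bulk RNA sequencing in MRC5 cells, an established line of human lung fibroblasts, in 4 groups of 2 libraries each. Cells carrying a control hairpin (shMock) or a hairpin against MTHFD2 (shMTHFD2) were sampled without or with TGF-β1. No further hairpin, rescue or untransduced line is among the libraries. Changes ascribed to the knockdown below are therefore differences between the lines, and the loss of MTHFD2 cannot be told apart from other differences. The labels give 4 ng of TGF-β1, without a volume, and 24 h of incubation. The treatment text stands on the control samples too, so the groups were taken from the sample titles and the treatment field. In 3 of the shMTHFD2 samples the genotype field names a gene other than MTHFD2, in a numbered series that looks like a filling error, and the titles were used there. The extraction text also mentions another cell line and another hairpin, and the measured MTHFD2 levels are given for each library so that the mapping can be judged. Libraries were made with a kit for mRNA and sequenced on an Illumina NovaSeq, per the labels. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical in part.

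The submitters' processing notes name STAR 2.7.1a, DESeq2 1.32.0 and the genome build GRCh38. The role of each tool, the read counter, the gene annotation, the use of strand and any filter are not given in the sources used here. The deposited table, although its name speaks of FPKM, holds whole-number counts for 60666 Ensembl gene IDs, 1 column per library. The values run without gaps from small whole numbers upward, the column totals differ between libraries, and median-of-ratios size factors computed on them differ from 1, so they are neither FPKM nor values normalised by the authors. Whether they are reads or rounded estimates is not stated. Reads that overlap more than 1 gene may have been shared out or dropped, so genes whose exons overlap another gene, or that have near-identical copies, are named as uncertain. Symbols came from the name table supplied with the reference files for 60437 IDs, and positions, strands and overlaps from GENCODE release 29, which holds 58420 of them.

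The test fixed before the data were examined was limma on log2 FPKM. Because the file holds counts, edgeR's quasi-likelihood test on the counts replaced it, a choice made after the values were seen. It ran in R 4.3.3 with edgeR 4.0.16, and camera and fry came from limma 3.58.1. Genes with a mean of at least 1 CPM (counts scaled to a common library total) over the 8 libraries were kept, which left 13493 genes. They hold 99.8 to 99.9% of the counts. Trimmed-mean (TMM) factors ran from 0.914 to 1.07, and the common biological coefficient of variation was 8.79%. All 8 libraries entered 1 fit with a mean per group, on 4 residual degrees of freedom. From it came 5 comparisons: shMTHFD2 against shMock with TGF-β1, the same without it, TGF-β1 against control in each line, and the interaction, which is the TGF-β1 response in shMTHFD2 minus that in shMock. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic and are approximate. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 2 libraries.

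Library totals ran from 18162738 to 22221927 counts, so a gene with 3 counts, used as the floor, stands at 0.135 to 0.165 CPM. Where both libraries of a group had no counts, the fold is a lower bound against 3 counts over the group. With 1 to 3 counts the ratio is given with an exact binomial 95% interval. These intervals and floors cover counting error only. The ratio of chi-square to its degrees of freedom between the replicates of a group was 6.47 to 11.2, so the replicates differed by more than counting error.

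Before the values were seen, 29 lists of genes were written down, of which 27 had at least 5 tested members. Each list was tested against the other genes with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Unless another test is named, an adjusted p of a list is that of camera with the preset correlation. Genes were named by a rule set at the same time. MTHFD2 is always given. For each comparison the rule takes the 10 highest and the 10 lowest fold changes among the genes past the threshold whose groups do not overlap (for the interaction, whose responses over the library pairs of 1 line lie all above or all below those of the other line). From each list it takes up to 2 higher and 2 lower members past the threshold, or, where none passed, the 2 with the highest expression, as values. IDs without a symbol, clone names, antisense names and pseudogenes were passed over, and near-identical copies count once. Of the list members, the text names those of the lists it describes, with preference for members called in each of the 8 fits that leave out 1 library. Results of a few genes that the rule selects are not reported here.

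The size of the TGF-β1 response in shMTHFD2 relative to shMock was read without a test. Genes differing by at least 1 on the log2 scale between 1 shMock TGF-β1 and 1 shMock control library were chosen, and their mean signed response was read in the other shMock libraries and in the shMTHFD2 libraries, for each of the 4 choices, on log2(CPM + 1).

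The alternatives fixed beforehand were other pseudocounts, no filter on low counts, a mean CPM of at least 5, median-of-ratios factors, quantile normalisation, a fit of the 2 compared groups alone, a replicate block, a 2-fold minimum, and leaving out each library in turn. The pseudocounts were run with limma on log2 CPM, and the planned rescaling to TPM became scaling on library totals. DESeq2 1.42.0, limma on log2 CPM, edgeR without an abundance trend, scaling on nuclear genes, and offsets for GC content and exon length were added after the data had been seen. A fit without 1 library leaves its group with a lone library, which is assumed to vary like the other groups. Replicate numbers did not pair the samples, since the differences between replicates were uncorrelated across groups (-0.0203 to 0.0687). Groups of 2 are too small for a test of outlying samples or of other splits of the libraries.

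The procedure was tested on simulated data with 200 changed genes among 13493. For the knockdown comparison with TGF-β1 it recovered 59.7% of the genes changed 1.5-fold, 71.6% of those changed 2-fold and 97.0% of those changed 4-fold. For the interaction it recovered 35.8%, 61.2% and 83.3%. False calls made up 8.43% and 9.77% of the calls, above the nominal 5%. A list of 30 genes lowered 1.5-fold was called by camera with either correlation and by fry, and a response set at 80% of its partner was read as 80.7%. The simulated genes varied independently, so the list result does not cover lists whose members vary together. Every changed gene was given the same share of its response, so differences between genes in that share were not covered. Alignments, splicing and sequence variants were not analysed here.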

Results

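Transcription was measured in MRC5 lung fibroblasts with a control hairpin (shMock) or a hairpin against MTHFD2 (shMTHFD2), each without and with TGF-β1, a cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. The purpose given for the series is to see what the loss of MTHFD2 does to transcription while the cells are being activated. Each of the 4 groups held 2 libraries, named here by group and replicate number. Total counts were 22221927 and 19593432 for shMock control, 20553084 and 18536494 for shMock TGF-β1, 20203456 and 18162738 for shMTHFD2 control, and 19829528 and 19982758 for shMTHFD2 TGF-β1. Between 18329 and 20087 gene IDs had counts above 0 in a library, and the 10 most abundant genes took 7.06 to 11.2% of the counts. Replicates correlated at 0.984 to 0.988 on log CPM across genes, which are not independent replicates. The first principal component held 54.8% of the variance and separated the libraries with TGF-β1 from those without it. The second held 15.5% and separated the lines.

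MTHFD2 (ENSG00000065911; GRCh38 chromosome 2, 74198562 to 74217565, plus strand, protein-coding) encodes a mitochondrial enzyme of folate one-carbon metabolism. Its level was 58.8 and 57.1 CPM in the shMock control libraries, 14.9 and 18.7 CPM in shMTHFD2 control, 256 and 258 CPM in shMock TGF-β1, and 93.8 and 91.9 CPM in shMTHFD2 TGF-β1. The knockdown was 3.46-fold without TGF-β1 (log2 fold change -1.79, SE 0.10, edgeR adjusted p = 3.5e-07) and 2.77-fold with it (-1.47, SE 0.09, edgeR adjusted p = 8.7e-07). TGF-β1 raised MTHFD2 4.43-fold in shMock and 5.54-fold in shMTHFD2, and the interaction test did not call a difference between these responses (0.32, SE 0.13, edgeR adjusted p = 0.35). With TGF-β1, the knockdown cells held more MTHFD2 mRNA (92.8 ± 1.36 CPM) than untreated shMock cells (58.0 ± 1.14 CPM), a difference that exceeds the spread between replicates and was not tested. A gene on the opposite strand overlaps MTHFD2, so its counts carry that uncertainty if reads were counted without strand.

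**Figure D1:**
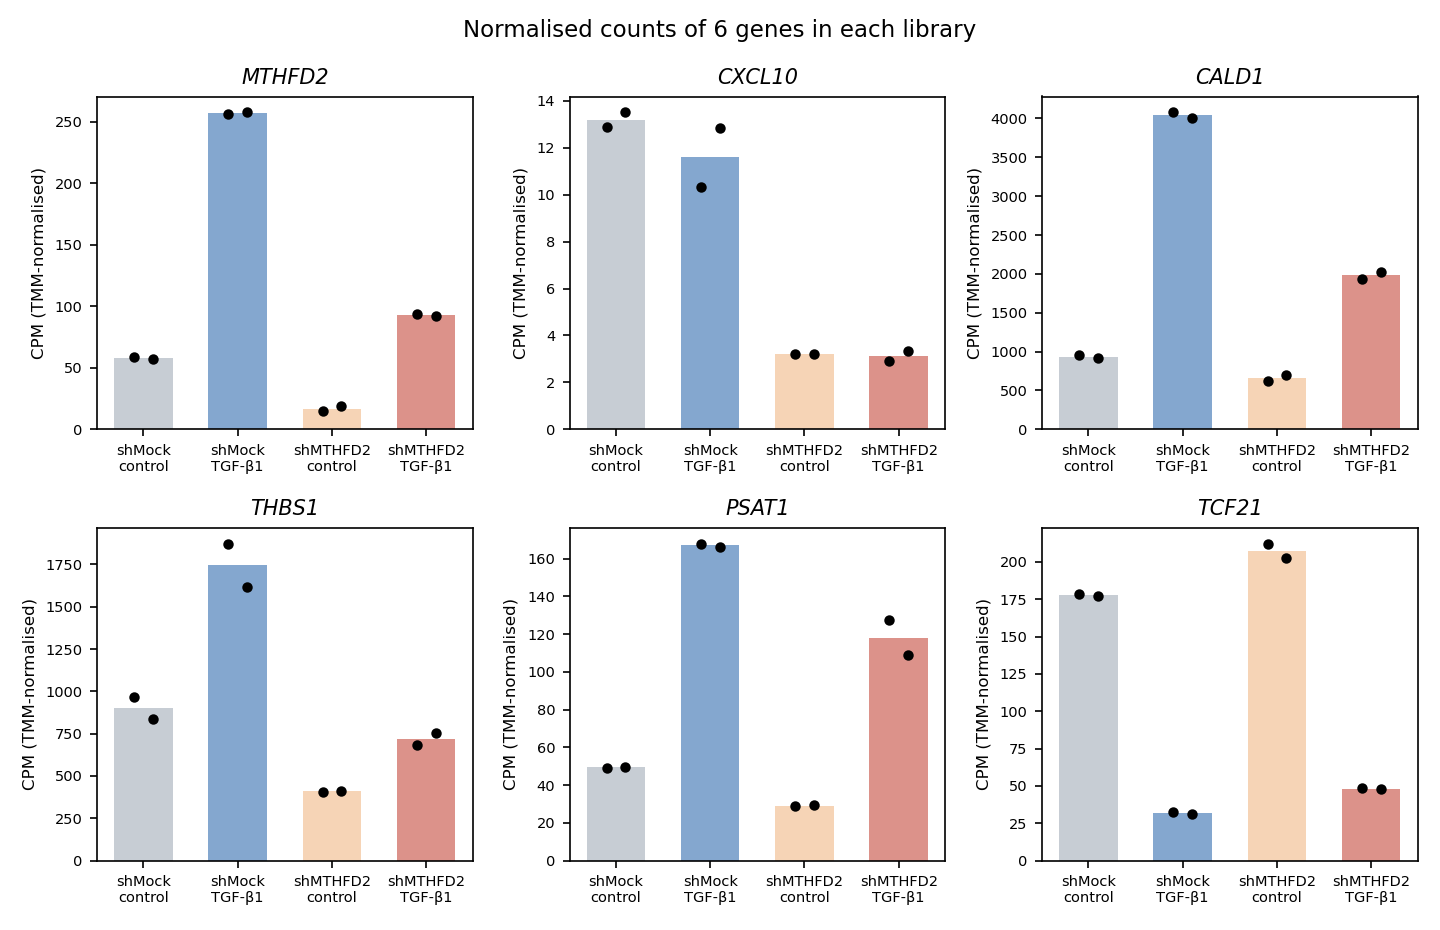
Levels in CPM of MTHFD2, CXCL10, CALD1, THBS1, PSAT1 and TCF21 in the 4 groups, with bars for the means of 2 libraries and points for the libraries. MTHFD2 averaged 58.0 and 257 CPM in shMock without and with TGF-β1, and 16.8 and 92.8 CPM in shMTHFD2.

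The main comparison, shMTHFD2 against shMock with TGF-β1, asks how the knockdown changes the activated fibroblast. The chemokine CXCL10, which interferon induces, was 3.69-fold lower in the knockdown (3.13 ± 0.315 against 11.6 ± 1.78 CPM), and 35 of 40 interferon-stimulated genes fell. Contractile genes and TGF-β targets were among the genes that fell. The actin-binding CALD1 was 2.04-fold lower (1981 ± 57.7 against 4041 ± 54.6 CPM), the matrix protein THBS1 2.43-fold lower (719 ± 49.3 against 1746 ± 180 CPM) and the matricellular factor CCN2 2.14-fold lower (693 ± 21.1 against 1486 ± 126 CPM). The edgeR quasi-likelihood test called 1762 of 13493 genes at an adjusted p under 0.05, of which 652 were higher and 1110 lower, and 130 also passed a 2-fold minimum. Without shMock TGF-β1 1 the test called 856 genes, without shMTHFD2 TGF-β1 1 it called 845, and without shMTHFD2 TGF-β1 2 it called 999. Scaling on library totals alone, which put the median log2 fold change of all genes at 0.10 against 0.01 with TMM, gave 1338 higher and 717 lower genes, so the balance between the directions depends on the scaling. Fold changes also rose with the GC content of the genes (Spearman 0.329 across genes), and with offsets that take this trend off, 1313 of the 1762 genes were called again.

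Among the 10 genes with the largest increases, ADH1B, an alcohol dehydrogenase, had a log2 fold change of 2.91 (2.11 ± 0.174 against 0.281 ± 0.171 CPM, SE 0.35, edgeR adjusted p = 0.0001). Its level in shMock TGF-β1 was near the floor of 3 counts (0.146 and 0.162 CPM in these libraries), so the size of this change is uncertain. The matrix protease ADAMTS15 followed (2.45, 6.85 ± 0.561 against 1.25 ± 0.339 CPM), then the homeobox gene MEOX2 (2.03), the ephrin receptor EPHA7 (1.89) and the mitochondrial biogenesis coactivator PPARGC1A (1.87). SLC38A11 (1.86), STOX2 (1.71), TBC1D3B (1.70) and FOXA1 (1.69) were also among them. The largest decreases were in TGFB2-OT1 (-2.63), FAM111B (-2.16), the neutrophil chemokine CXCL8 (-2.12), ADAMTS19 (-2.09), CXCL11 (-2.02), RGS7 (-1.95), CXCL10 (-1.88), the cytokine IL6 (-1.87), the cytidine deaminase APOBEC3B (-1.81) and the mitotic ubiquitin enzyme UBE2C (-1.81). IL6 was 3.67-fold lower (1.5 ± 0.545 against 5.53 ± 0.133 CPM, SE 0.35, edgeR adjusted p = 0.0026). ADH1B, ADAMTS15, EPHA7, CXCL10 and IL6 were called in each fit that left out 1 library, and 15 of the 20 genes that the rule selects lost their call in at least 1 of them. The losses numbered 11 without shMTHFD2 TGF-β1 1 (edgeR adjusted p = 0.0532 to 0.267), 9 without shMTHFD2 TGF-β1 2 (0.0585 to 0.196), 11 without shMock TGF-β1 1 (0.0547 to 0.222), 9 without shMock TGF-β1 2 (0.0555 to 0.123), and SLC38A11 without shMTHFD2 control 1 (0.0502). Exons of ADH1B, TGFB2-OT1 and APOBEC3B overlap another gene on the same strand, SLC38A11, FOXA1, ADAMTS19, RGS7, IL6 and APOBEC3B one on the opposite strand, and TBC1D3B has close paralogs, so these values are uncertain.

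The interferon-stimulated genes had the smallest camera p of the 27 lists in this comparison. Of 40 interferon-stimulated genes tested, 35 fell and 5 did not pass (37 lower adjusted over the list alone), with a median log2 fold change of -0.84, and CXCL10 and CXCL11 fell most. CXCL11 lost its call without shMTHFD2 TGF-β1 2 (edgeR adjusted p = 0.0994) and without shMock TGF-β1 2 (edgeR adjusted p = 0.0849). The list was called lower (camera adjusted p = 1.1e-61; adjusted p = 0.143 with an estimated correlation). Among 23 genes of antigen presentation and immune checkpoints, 7 fell and 1 rose (7 and 2 adjusted over the list alone). The checkpoint ligands CD274, which encodes PD-L1 (-1.10, 5.25 ± 0.704 against 11.2 ± 1.49 CPM, edgeR adjusted p = 0.0048), and PDCD1LG2 (-1.05) were lower. The list's call (adjusted p = 0.0185; adjusted p = 0.28 with an estimated correlation) was lost without shMock TGF-β1 2 (adjusted p = 0.159), where 4 members fell. The member that rose, TNFRSF14, lost its call without shMTHFD2 TGF-β1 1 or 2 or shMock TGF-β1 1. Of 20 inflammatory cytokines and NF-κB targets, 5 fell and 15 did not pass (5 lower adjusted over the list alone), with IL6 and CXCL8 lowest (adjusted p = 0.00955; adjusted p = 0.242 with an estimated correlation). Without shMTHFD2 TGF-β1 1 or shMock TGF-β1 1 the count was 3, without shMock TGF-β1 2 it was 2, and without shMTHFD2 TGF-β1 2 the list lost its call (adjusted p = 0.0536).

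The myofibroblast programme was read through contractile genes, TGF-β targets and matrix genes. Of 28 contractile genes, 20 fell and 8 did not pass (23 lower adjusted over the list alone), among them TPM1, a tropomyosin (-1.14, 1111 ± 41.5 against 2447 ± 443 CPM), and CALD1 (-1.03, SE 0.09, edgeR adjusted p = 6.3e-06). The count was 12 without shMTHFD2 TGF-β1 2 and 12 without shMock TGF-β1 1, and the list was called lower (adjusted p = 7.3e-20; adjusted p = 0.143 with an estimated correlation). Of 33 TGF-β/SMAD targets, 15 fell and 18 did not pass (16 lower and 2 higher adjusted over the list alone). CCN2 (-1.10, SE 0.09, edgeR adjusted p = 3.8e-06) and INHBA, the activin A subunit (-0.90, 194 ± 4.31 against 363 ± 0.161 CPM), led them. Without shMTHFD2 TGF-β1 2 the count was 8, and the list was called lower (adjusted p = 5.2e-11; adjusted p = 0.155 with an estimated correlation). Of 22 matrix proteases and inhibitors, 7 fell and 15 did not pass (9 lower adjusted over the list alone), with the inhibitor TIMP3 2.22-fold lower (102.4 ± 1.2 against 228 ± 27 CPM) and ADAMTS6 at -0.68 (adjusted p = 9.0e-06; adjusted p = 0.206 with an estimated correlation). Of 24 collagens, 3 fell and 21 did not pass (3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.781), with a median of 0.01 but a mean of -0.06 and a test pointing down. COL15A1 (-0.42) and COL12A1 (-0.39) were lowest. COL12A1 lost its call without shMTHFD2 TGF-β1 1 or 2 or shMock TGF-β1 1, COL15A1 without shMTHFD2 TGF-β1 1 or shMock TGF-β1 1. Without these last libraries no collagen fell in edgeR, and without shMTHFD2 TGF-β1 2 the count was 1. GC and length offsets gave 5 lower and 1 higher, and 1 also rose without either shMTHFD2 control library or without shMock TGF-β1 1. The median turned slightly negative under median-of-ratios factors and nuclear scaling. Of 31 matrix glycoproteins, 4 fell and 2 rose (5 and 2 adjusted over the list alone), with THBS1 at -1.28, CTHRC1 at -0.56 and the laminin chain LAMA4 at 0.63, and that list was not called either (adjusted p = 0.06). Its lower count was 7 without shMock TGF-β1 2 and 7 with GC and length offsets, and its higher count was 1 with the offsets and 1 without any single TGF-β1 library.

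Metabolic and stress lists include those of the pathway that MTHFD2 belongs to. Of 22 folate and serine enzymes other than MTHFD2, 3 fell and 1 rose (3 lower adjusted over the list alone), and the list was not called (adjusted p = 0.117). The serine enzyme PSAT1 (-0.50, 118 ± 13 against 167 ± 1.09 CPM, edgeR adjusted p = 0.0013) and ALDH1L2, a mitochondrial folate enzyme (-0.53), were lower. GC and length offsets gave 5 lower members. The risen member lost its call with these offsets and in some fits that left out 1 library. Of 15 purine synthesis genes, 2 fell and 13 did not pass (2 lower adjusted over the list alone), and the list was not called (adjusted p = 0.305). PRPS1, which makes the precursor of purine synthesis, was at -0.76 (83.3 ± 3.24 against 141 ± 2.28 CPM). IMPDH1 (-0.35) lost its call without shMTHFD2 TGF-β1 1 or 2 or shMock TGF-β1 1, which left a count of 1. Of 30 targets of the ATF4 stress response, which many amino-acid genes belong to, 12 fell and 18 did not pass (13 lower adjusted over the list alone), with ATF3 (-0.84, 24.5 ± 1.16 against 43.8 ± 1.47 CPM) and the lipoprotein receptor VLDLR (-0.91) lowest (adjusted p = 2.2e-07; adjusted p = 0.155 with an estimated correlation). Of 18 genes of the unfolded protein response, 7 fell and 11 did not pass (8 lower adjusted over the list alone), among them the chaperone HSPA5 (-0.54, 510 ± 18.3 against 742 ± 39.4 CPM) and the transcription factor XBP1 (-0.51). That list was called lower (adjusted p = 1.3e-05; adjusted p = 0.242 with an estimated correlation), and its count was 3 without shMTHFD2 TGF-β1 1 and 3 without shMock TGF-β1 1. Of 18 NRF2 antioxidant genes, 4 rose and 14 did not pass (4 higher adjusted over the list alone), led by the reductase AKR1C1 (0.76, 35.5 ± 1.84 against 20.9 ± 0.782 CPM). The list was called higher (adjusted p = 0.00191; adjusted p = 0.28 with an estimated correlation), and 2 members rose without shMTHFD2 TGF-β1 1 or without shMock TGF-β1 1.

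Proliferation genes, growth factors and markers of other cells were read in the same way. Of 27 genes of DNA replication, 7 fell. Proliferation genes were lower in other comparisons too. Without TGF-β1, 7 of 29 mitotic and 9 of 27 replication genes were lower in shMTHFD2, and TGF-β1 in shMock lowered 13 and 12 of them. The counts for shMTHFD2 against shMock were smaller without several of the single libraries. Of 29 mitotic genes, 11 fell and 18 did not pass (18 lower adjusted over the list alone), with a median of -0.71 (adjusted p = 1.2e-07; adjusted p = 0.242 with an estimated correlation). The count was 5 without shMTHFD2 TGF-β1 1 and 1 without shMock TGF-β1 1. UBE2C (-1.81) and BIRC5, an inhibitor of apoptosis needed in mitosis (-1.22), were lowest, and both lost their call without shMTHFD2 TGF-β1 2 or shMock TGF-β1 1, UBE2C also without shMTHFD2 TGF-β1 1. Of 34 growth factors and modulators of Wnt, BMP and Hedgehog signals, 12 fell and 1 rose (16 and 1 adjusted over the list alone), with TGFB2 (-0.97) and the Wnt inhibitor DKK1 (-0.89) lowest (adjusted p = 2.5e-05; adjusted p = 0.242 with an estimated correlation). The count of 12 became 6 without shMTHFD2 TGF-β1 1 and 7 without shMock TGF-β1 1. The member that rose, PDGFRA (0.28), lost its call in each of the 8 fits that left out 1 library and with nuclear scaling. GC and length offsets called 2 members higher. The fibroblast transcription factor TCF21 was higher (0.59, 48.2 ± 0.652 against 32 ± 1.02 CPM) and the surface marker THY1 lower (-0.42), while the 13 fibroblast markers as a list were not called (adjusted p = 0.824). Of 8 genes of smooth muscle, pericytes and mesothelium, 1 fell and 7 did not pass (1 lower adjusted over the list alone), the adhesion molecule MCAM (-0.65, 136 ± 6.47 against 213 ± 0.657 CPM), and that list was not called (adjusted p = 0.376). Markers of other cells gave values of 0.25 for KDR and -0.16 for TEK in endothelium and -0.20 for the macrophage marker CD68 (edgeR adjusted p = 0.16), and KRT8 stood at 0.24 and KRT18 at 0.00. Of 7 histone mRNAs, read as a sign of RNA capture, 2 rose (2 adjusted over the list alone; adjusted p = 0.00647; adjusted p = 0.418 with an estimated correlation), and fry did not call the list (adjusted p = 0.0652). The risen members were H2BC5 (1.58), which lost its call without shMock TGF-β1 1, and H2AC6 (0.63). The ribosomal protein genes were not called (adjusted p = 0.266). THBS1, TPM1, CCN2, LAMA4, ALDH1L2, VLDLR, DKK1, TCF21 and THY1 overlap a gene on the opposite strand, TGFB2 and PDGFRA one on the same strand, and MCAM genes on both strands, so reads from these neighbours may be counted with them. AKR1C1 and the histone genes have close paralogs.

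**Figure D2:**
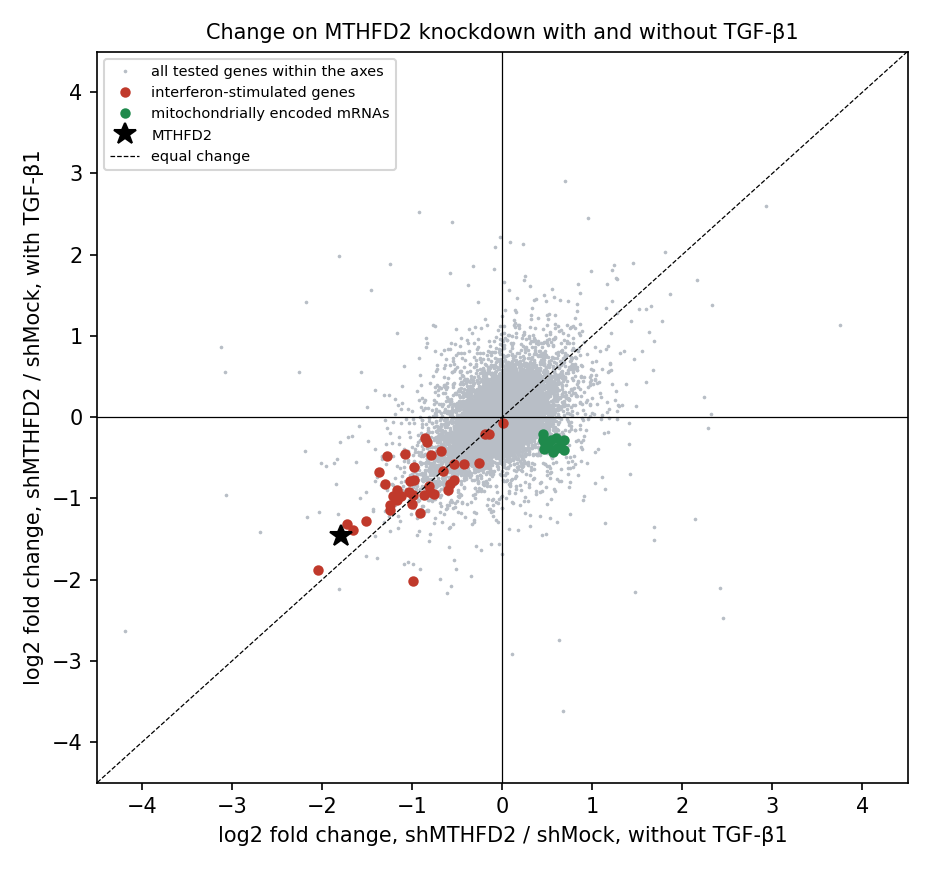
Log2 fold change of each tested gene in shMTHFD2 against shMock, without TGF-β1 on the horizontal axis and with it on the vertical axis, with interferon-stimulated genes in red, mitochondrially encoded mRNAs in green and MTHFD2 as a star; 8 genes lie outside the axes. The red points sit below 0 on both axes for most of the 40 genes.

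The comparison of shMTHFD2 with shMock without TGF-β1 asks what the knockdown does in cells that were not activated. CXCL10 was 4.12-fold lower (3.2 ± 0.00591 against 13.2 ± 0.437 CPM) and IFIT2, an interferon-induced RNA-binding protein, 3.3-fold lower (200 ± 35.5 against 659 ± 37.3 CPM). The serine enzyme PSAT1 was lower as well (29.1 ± 0.288 against 49.3 ± 0.255 CPM), as were CCN2 (245 ± 5.68 against 486 ± 8.27 CPM) and the Wnt inhibitor SFRP1 (59.5 ± 1.39 against 118 ± 0.15 CPM). The edgeR test called 1543 genes, of which 438 were higher and 1105 lower, and 111 also passed a 2-fold minimum. Without shMock control 1 it called 962 genes, without shMock control 2 it called 654, and without shMTHFD2 control 2 it called 638. The split was 755 higher and 740 lower with scaling on library totals, and 687 higher and 892 lower with quantile normalisation.

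Among the largest increases, the read-through INO80B-WBP1 had no counts in the shMock libraries and 268 in shMTHFD2, at least 92.8-fold higher against the floor. SNURF (2.32), DLEU2L (1.86), MEOX2 (1.81), NUTM2B (1.77), FAM106A (1.67), ZNF483 (1.63), the chloride channel CFTR (1.59, 6.58 ± 0.337 against 2.17 ± 0.489 CPM, edgeR adjusted p = 0.0013), ZNF185 (1.46) and EPHA7 (1.45) followed. The largest decreases were in TGFB2-OT1 (-4.19), the membrane repair gene DYSF (-2.69), the smooth muscle RNA CARMN (-2.19), the growth factor PDGFB (-2.17, 0.392 ± 0.0303 against 1.79 ± 0.0512 CPM, edgeR adjusted p = 0.0048), CXCL10 (-2.04), the double-stranded RNA sensor TLR3 (-2.03), PIMREG (-1.87), FAM156A (-1.84), the keratin-associated protein gene KRTAP1-5 (-1.82) and MTHFD2 itself. Apart from MTHFD2, CFTR, TGFB2-OT1, PDGFB and CXCL10 kept their call in each fit that left out 1 library, and 15 of the 19 lost it in at least 1. The losses numbered 6 without shMTHFD2 control 1 (edgeR adjusted p = 0.0540 to 0.130), 13 without shMTHFD2 control 2 (0.0539 to 0.275), 7 without shMock control 1 (0.0515 to 0.0905) and 12 without shMock control 2 (0.0652 to 0.355). INO80B-WBP1, SNURF, DLEU2L, FAM106A, TGFB2-OT1, CARMN and IFIT2 overlap another gene on the same strand, and CFTR and PIMREG one on the opposite strand. NUTM2B and FAM156A have near-identical copies.

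Several lists described for the comparison with TGF-β1 were called here as well. Of 40 interferon-stimulated genes, 35 fell and 5 did not pass (36 lower adjusted over the list alone), with a median of -0.98 (adjusted p = 2.2e-80; adjusted p = 0.0897 with an estimated correlation). Of 23 genes of antigen presentation and checkpoints, 10 fell and 13 did not pass (12 lower adjusted over the list alone), among them LGALS9, which encodes galectin-9 (-1.41), and the immunoproteasome subunit PSMB9 (-0.97), both with a same-strand overlap (adjusted p = 5.9e-08; adjusted p = 0.0897 with an estimated correlation). Of 28 contractile genes, 15 fell and 13 did not pass (18 lower adjusted over the list alone), with the smooth muscle actin ACTG2 (-0.90, 35 ± 2.15 against 65.3 ± 3.74 CPM) and the calponin CNN1 (-0.85) lowest. The count was 8 without shMTHFD2 control 2 (adjusted p = 2.8e-13; adjusted p = 0.095 with an estimated correlation). Of 33 TGF-β/SMAD targets, 12 fell and 21 did not pass (14 lower adjusted over the list alone), with CCN2 at -0.99 and its relative CCN1 at -0.93 (157 ± 8.9 against 299.6 ± 7.17 CPM; adjusted p = 1.4e-09 for the list; adjusted p = 0.0977 with an estimated correlation). Of 31 matrix glycoproteins, 9 fell and 2 rose (12 and 4 adjusted over the list alone), led by THBS1 (-1.14) and CTHRC1 (-0.61). The list's call (adjusted p = 0.0023; adjusted p = 0.437 with an estimated correlation) was lost without shMock control 1 (adjusted p = 0.103) and with fry (adjusted p = 0.0803), and its lower count was 4 without shMTHFD2 control 2 and 5 without shMock control 1 or 2. The risen members, VCAN and LAMA4, did not hold either, since 1 was left without shMTHFD2 control 1 or without either shMTHFD2 TGF-β1 library and neither passed without shMTHFD2 control 2 or shMock control 2.

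Markers of other cells and signs of RNA quality were read in this comparison as well. Of 8 genes of smooth muscle, pericytes and mesothelium, 1 fell and 7 did not pass (2 lower adjusted over the list alone), the adhesion molecule MCAM (-0.82, 89.4 ± 5.79 against 158 ± 2.35 CPM). The list's call (adjusted p = 0.0448; adjusted p = 0.168 with an estimated correlation) was lost without shMock control 1 (adjusted p = 0.115), without shMTHFD2 control 2 (adjusted p = 0.0724) and with limma on log2(CPM + 0.1) (adjusted p = 0.11). CD68 was lower (-0.45, 75.1 ± 0.953 against 102.8 ± 3.97 CPM, edgeR adjusted p = 0.0025). KDR stood at -0.26 and TEK at -0.04 in endothelium, and KRT18 at -0.23 and KRT8 at -0.22. Of 7 histone mRNAs, 1 rose and 6 did not pass (1 higher adjusted over the list alone), H2AC6 (0.77), and the list had a median of 0.49 (adjusted p = 0.0164; adjusted p = 0.432 with an estimated correlation). Without shMTHFD2 control 1 that median was 0.17 and the call was lost (adjusted p = 0.387), and fry did not call the list (adjusted p = 0.131). The ribosomal protein genes were not called (adjusted p = 0.119). MCAM and CD68 overlap genes on both strands.

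Metabolic, stress and growth factor lists gave the following counts. Of 22 folate and serine enzymes, 5 fell and 1 rose (6 and 1 adjusted over the list alone), with PSAT1 (-0.76, edgeR adjusted p = 9.7e-05) and PHGDH, the first enzyme of serine synthesis (-0.69, edgeR adjusted p = 0.00023), lowest (adjusted p = 0.00259; adjusted p = 0.0973 with an estimated correlation). Without shMTHFD2 control 2 the lower count was 3, and the member that rose, MTR (0.30), lost its call without that library, without either shMock control library, without shMTHFD2 TGF-β1 2 and with GC and length offsets. Of 30 ATF4 targets, 17 fell and 1 rose (22 and 2 adjusted over the list alone), including ATF3 (-1.04, 12.3 ± 0.463 against 25.3 ± 1.73 CPM), and the list was called lower (adjusted p = 2.8e-13; adjusted p = 0.0897 with an estimated correlation). Its lower count was 10 without shMTHFD2 control 2 and 11 without shMock control 1. The cystine transporter SLC7A11 (0.40), its risen member, lost its call without shMTHFD2 control 2 or shMock control 2, and GC and length offsets gave 2 higher members. Of 18 genes of the unfolded protein response, 6 fell and 12 did not pass (11 lower and 2 higher adjusted over the list alone), with XBP1 at -0.65 and HSPA5 at -0.61 (adjusted p = 0.000129; adjusted p = 0.18 with an estimated correlation), and 3 fell without shMTHFD2 control 2 or without shMock control 2. Of 34 growth factors and modulators, 15 fell and 1 rose (19 and 3 adjusted over the list alone), with DKK1 (-1.28, 14.8 ± 1.62 against 36 ± 1.37 CPM) and SFRP1 (-0.99) lowest (adjusted p = 3.1e-08; adjusted p = 0.114 with an estimated correlation). Their count was 8 without shMTHFD2 control 1, 9 without shMTHFD2 control 2, 7 without shMock control 1 and 9 without shMock control 2, and the risen member, PDGFRA (0.30), lost its call without shMTHFD2 control 2 or either shMock control library.

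Of the 13 mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and have copies in the nuclear genome, 10 rose without TGF-β1 and 3 did not pass (13 higher adjusted over the list alone), with a median of 0.54, beside a histone median of 0.49 in the same comparison. MT-ND5 (0.68, 3325 ± 581 against 2075 ± 707 CPM, edgeR adjusted p = 0.019) and MT-ND2 (0.64, edgeR adjusted p = 0.012) rose most. The list was called higher by camera (adjusted p = 1.3e-09; adjusted p = 0.18 with an estimated correlation) but not by fry (adjusted p = 0.105). No member was called by edgeR without shMTHFD2 control 2 or without shMock control 2, although 13 had an unadjusted p under 0.05 with all libraries, and DESeq2 called none of them. The share of counts on these mRNAs was 5.001 and 3.53% in shMock control, 5.68 and 7.04% in shMTHFD2 control, 4.03 and 4.21% in shMock TGF-β1, and 3.51 and 3.63% in shMTHFD2 TGF-β1. With TGF-β1 the list was called lower in shMTHFD2 by camera (median -0.33, adjusted p = 0.0035; adjusted p = 0.515 with an estimated correlation) but not by fry (adjusted p = 0.297), while no member passed in edgeR or DESeq2 and 6 had an unadjusted p under 0.05. Values there were -0.21 for MT-CO1 and -0.37 for MT-ND4. Leaving out either shMock control library called 3 members lower there, and leaving out either shMTHFD2 control library called 1.

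The TGF-β1 response of shMock cells serves as the reference for fibrotic activation. The myofibroblast marker ACTA2, smooth muscle actin, was 12.6-fold higher (1296 ± 26.6 against 102.8 ± 2.15 CPM), the oxidase NOX4 23.5-fold higher (50 ± 1.84 against 2.12 ± 0.273 CPM) and the vasoconstrictor gene EDN1 26.8-fold higher (28.5 ± 1.21 against 1.06 ± 0.0302 CPM). Elastin, ELN, was 76.8-fold higher (45.6 ± 1.6 against 0.586 ± 0.0612 CPM). The hyaluronan-degrading CEMIP was 16.4-fold lower (42.3 ± 6.57 against 694 ± 51.4 CPM) and NPTX1, a neuronal pentraxin, 8.39-fold lower (142 ± 13.1 against 1193 ± 7.42 CPM). The edgeR test called 4776 genes, of which 2333 were higher and 2443 lower, and 1016 also passed a 2-fold minimum. Scaling on library totals put the median log2 fold change of all genes at -0.16 here (-0.02 with TMM) and at -0.12 for shMTHFD2 (-0.01 with TMM), and gave 1570 higher and 3932 lower genes in shMock.

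WNT11, a Wnt ligand, had no counts in shMock control and 202 with TGF-β1, at least 79.1-fold higher. ZPLD1 rose from 1 to 100 counts, a ratio of 118 (95% interval 20.6 to 4688), and the growth factor IGF1 from 2 to 115, a ratio of 67.6 (18.3 to 565). ELN (6.26), RASGRP3 (5.53), B3GALT1 (5.39), LMCD1 (5.15), the potassium channel KCNH1 (4.98), EDN1 (4.74) and SYTL5 (4.58) completed the 10 largest increases. The decreases were led by ADH1B (-6.33), SLC7A14 (-4.58), SERPINB2, an inhibitor of plasminogen activators (-4.36), CEMIP (-4.03), the interleukin-6 receptor IL6R (-3.59), RASL11A (-3.27), SLC38A11 (-3.24), the monocyte chemokine CCL2 (-3.21), ZC3H12B (-3.10) and NPTX1 (-3.07). None of these 20 lost its call in a fit that left out 1 library. ADH1B, SERPINB2 and KCNH1 overlap another gene on the same strand, and ACTA2, ELN, WNT11, IGF1, RASGRP3, B3GALT1, LMCD1, CEMIP, SLC7A14 and SLC38A11 one on the opposite strand.

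By group, 26 of 28 contractile genes rose and 1, the myosin kinase MYLK, fell (the same counts adjusted over the list alone), and 28 of 33 TGF-β/SMAD targets rose and 4 fell (28 and 4 adjusted over the list alone), with NOX4 at 4.56 and the inhibitor BAMBI at -2.19. Both lists were called higher with the preset correlation (adjusted p = 8.0e-34 and 1.6e-43) and with an estimated one (adjusted p = 0.0382 with an estimated correlation for each). The lower SMAD count was 2 without shMock TGF-β1 2 and 2 without shMock control 1. Of 30 ATF4 targets, 22 rose and 4 fell (22 and 4 adjusted over the list alone), with asparagine synthetase, ASNS, at 2.36 (152 ± 4.75 against 29.5 ± 5.51 CPM; adjusted p = 2.7e-12 for the list; adjusted p = 0.0749 with an estimated correlation). Of 18 genes of the unfolded protein response, 15 rose and 3 did not pass (15 adjusted over the list alone), XBP1 among them at 1.38 (adjusted p = 2.5e-06; adjusted p = 0.163 with an estimated correlation). In the folate and serine list 7 rose and 6 fell (7 and 8 adjusted over the list alone), with PSAT1 3.39-fold higher (167 ± 1.09 against 49.3 ± 0.255 CPM), ALDH1L2 at 1.79 and the cytosolic SHMT1 and TYMS both at -0.86. That list was not called (adjusted p = 0.0618), and its median was -0.01 where its mean was 0.13 and the test pointed up. The median turned positive under quantile, median-of-ratios and nuclear scaling.

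Among matrix genes, 14 of 24 collagens rose and 6 fell (14 and 6 adjusted over the list alone), with COL10A1 at 3.92 and COL13A1 at -1.13 (adjusted p = 6.5e-05; adjusted p = 0.359 with an estimated correlation). Of 31 matrix glycoproteins, 19 rose and 6 fell (20 and 7 adjusted over the list alone), with versican, VCAN, 14.8-fold higher (889 ± 129 against 60.2 ± 4.98 CPM; adjusted p = 2.5e-17 for the list; adjusted p = 0.163 with an estimated correlation). Of 22 proteases and inhibitors, 11 rose and 4 fell (11 and 4 adjusted over the list alone), with ADAM12 at 3.76, ADAM19 at 3.63 and ADAMTS1 at -2.42 (adjusted p = 0.000106; adjusted p = 0.163 with an estimated correlation). NRF2 antioxidant genes were lower, with 16 of 18 falling and 1 rising (16 and 2 adjusted over the list alone). AKR1C1 fell (-1.95, 20.9 ± 0.782 against 80.7 ± 10 CPM) and the glutamate-cysteine ligase subunit GCLC rose (0.79; adjusted p = 4.9e-14 for the list; adjusted p = 0.108 with an estimated correlation), and without shMock TGF-β1 2 the risen count was 2. Of 23 genes of antigen presentation and checkpoints, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with PSMB9 at -1.14 and PDCD1LG2 at 0.73 (adjusted p = 0.000598; adjusted p = 0.163 with an estimated correlation). The rise of CD274 (0.60) lost its call without any single shMock library, which left 1 risen member, as did GC and length offsets. Of 40 interferon-stimulated genes, 14 fell and 2 rose (14 and 2 adjusted over the list alone), with GBP2 at -0.83 and GBP1 at 0.86. That call (adjusted p = 0.0402; adjusted p = 0.755 with an estimated correlation) was lost without shMock control 1 (adjusted p = 0.0572), without shMock TGF-β1 1 (adjusted p = 0.429) and with fry (adjusted p = 0.099). The fibroblast factor TCF21 fell by 2.47 on the log2 scale. Of 5 tested endothelial markers, 3 fell (3 adjusted over the list alone), with KDR at -2.29 and TEK at -1.10. Camera called the list lower (adjusted p = 0.0183, and adjusted p = 0.163 with an estimated correlation). CD68, the only leukocyte marker tested, was lower as well (-0.88). The rest of the endothelial and leukocyte lists was not among the tested genes, so these falls do not show a change in other cells. Of 3 epithelial markers, too few for a list test, 2 fell (2 adjusted over the list alone), the retinal dehydrogenase ALDH1A1 (-0.99) and the keratin KRT8 (-0.53), and KRT8 lost its call without shMock TGF-β1 2 or shMock control 1. Of 28 ribosomal protein genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), with RPLP2 at -0.50 and RPS14 at 0.28, and the list was not called (adjusted p = 0.234). Its lower count was 3 without shMock TGF-β1 2, 2 without shMock control 2 and 2 with GC and length offsets, which called 2 higher, and RPS14 lost its call without shMock TGF-β1 1 or shMock control 1. Of the 8 genes of smooth muscle, pericytes and mesothelium, MCAM rose (0.43) and CSPG4 fell (-0.76; 1 and 1 adjusted over the list alone), 2 fell without shMock TGF-β1 1, and the list was not called (adjusted p = 0.591). The histone mRNAs were not called as a list (median -0.30, adjusted p = 0.598). ASNS and GBP2 overlap another gene on the same strand, GCLC, PSMB9, CD68, MCAM and RPLP2 genes on both strands, and KRT8, CSPG4, MYLK, ALDH1L2, VCAN, ADAM19 and TCF21 one on the opposite strand.

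**Figure D3:**
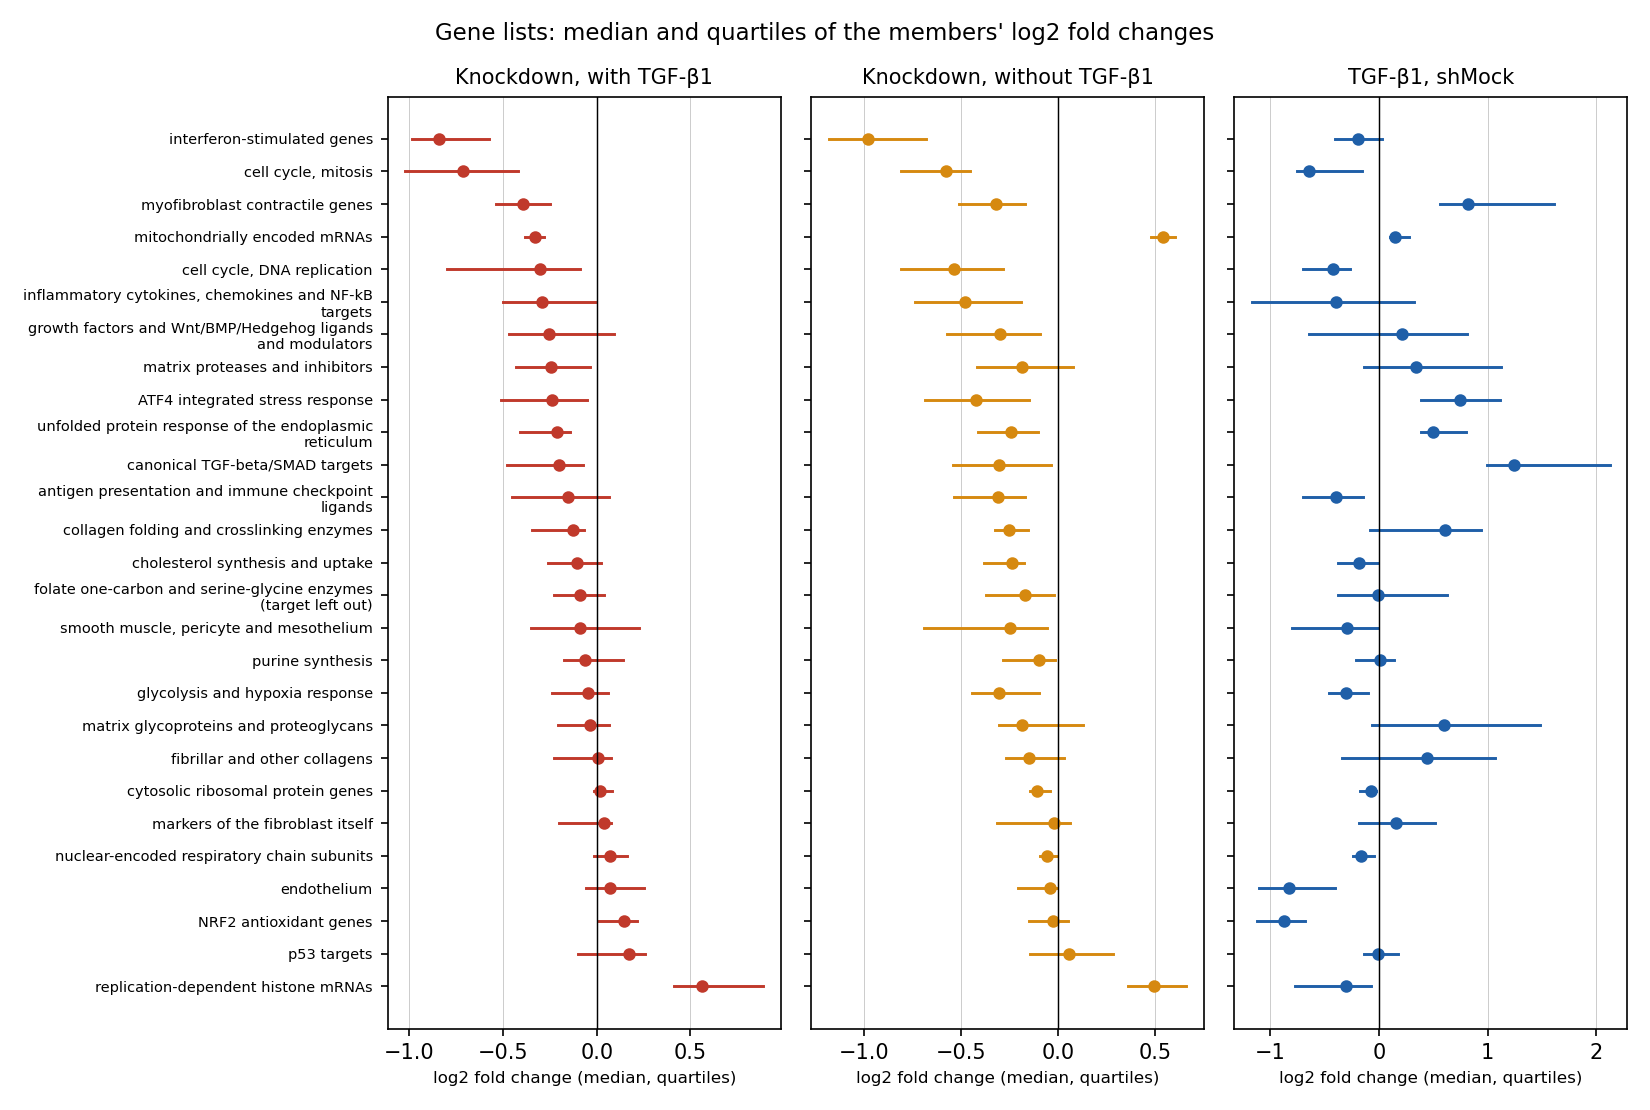
Median log2 fold change of each gene list, with lines from the lower to the upper quartile of its members, for the knockdown with TGF-β1, the knockdown without it and TGF-β1 in shMock. The interferon-stimulated genes have medians of -0.84 and -0.98 in the knockdown panels.

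The same treatment in shMTHFD2 cells asks whether activation proceeds when MTHFD2 is lower than in equally treated shMock cells. With TGF-β1 they held 92.8 CPM of MTHFD2, above the 58.0 CPM of untreated shMock cells, so activation at low MTHFD2 was not observed. ACTA2 was 9.36-fold higher with TGF-β1 (852 ± 12.5 against 91 ± 4.18 CPM), ELN 159-fold higher (39.7 ± 6.71 against 0.237 ± 0.189 CPM) and the collagen gene COL1A1 2.49-fold higher (25501 ± 64.9 against 10233 ± 861 CPM). The growth factor binding protein IGFBP3 was higher as well (3.96, 773 ± 50.8 against 49.8 ± 2.26 CPM). The shMTHFD2 control level of ELN was near the floor of 3 counts (0.148 and 0.165 CPM in these libraries), so the size of its fold is uncertain. The interaction test did not call ELN. The edgeR test called 3214 genes, of which 1725 were higher and 1489 lower, and 779 also passed a 2-fold minimum. Scaling on library totals gave 1222 higher and 2455 lower. IGF1 went from no counts to 184, at least 64.0-fold higher, WNT11 from 1 to 200 (ratio 209, 95% interval 37.0 to 8280) and ZPLD1 from 2 to 82 (ratio 42.8, 11.5 to 359). RASGRP3 (5.51), B3GALT1 (5.35), LMCD1 (5.22), CARMN (4.90), the Wnt receptor FZD8 (4.90) and NOX4 (4.70) rose most besides ELN. MKKS, here the ID ENSG00000285508 that overlaps another gene on the same strand, fell from 85 counts to none, at least 27.2-fold lower. ADH1B (-4.11), SLC7A14 (-4.11), SERPINB2 (-3.75), RASL11A (-3.73), the fatty acid receptor CD36 (-3.52), CEMIP (-3.41), PLXNC1 (-3.40), GRIK4 (-3.12) and the carbonic anhydrase CA12 (-3.08) fell most besides it. None of these 20 lost its call in a fit that left out 1 library. CARMN and FZD8 also overlap another gene on the same strand.

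Of 28 contractile genes, 25 rose and 1 fell (26 and 1 adjusted over the list alone), and of 33 TGF-β/SMAD targets, 28 rose and 1, the transcription factor SNAI2, fell (29 and 3 adjusted over the list alone). Without shMTHFD2 control 1, or with GC and length offsets, 2 SMAD targets fell. Of 30 ATF4 targets, 22 rose and 1 fell (22 and 2 adjusted over the list alone), with ASNS at 2.40, and 2 fell without shMTHFD2 TGF-β1 1. These 3 lists were called higher with the preset correlation (adjusted p = 1.1e-37, 1.7e-53 and 1.5e-19) and with an estimated one (adjusted p = 0.0267, 0.0246 and 0.0267 with an estimated correlation). PSAT1 rose by 2.02 on the log2 scale, ALDH1L2 by 1.88, VCAN by 3.32 and COL10A1 by 4.06. Of 18 NRF2 genes, 15 fell and 1 rose (15 and 1 adjusted over the list alone), with AKR1C1 at -1.90 (adjusted p = 1.3e-12; adjusted p = 0.112 with an estimated correlation). The 13 mitochondrially encoded mRNAs all fell (13 adjusted over the list alone), with a median of -0.72, and MT-ATP8 (-0.81, 394 ± 1.71 against 691 ± 41.7 CPM) and MT-ATP6 (-0.79), which overlap each other, fell most. Camera called that list lower (adjusted p = 2.5e-05; adjusted p = 0.404 with an estimated correlation), fry did not (adjusted p = 0.064), and DESeq2 called 11 of the 13.

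**Figure D4:**
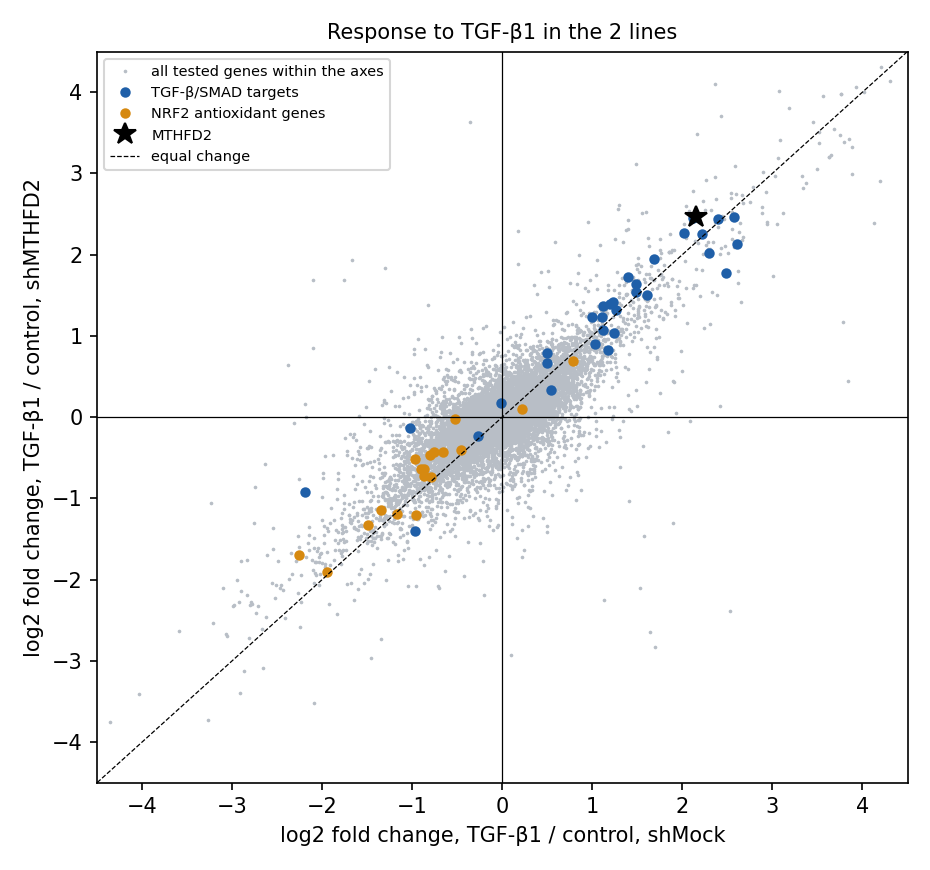
Log2 fold change of each tested gene with TGF-β1 against control, in shMock on the horizontal axis and in shMTHFD2 on the vertical axis, with TGF-β/SMAD targets in blue, NRF2 antioxidant genes in orange and MTHFD2 as a star; 27 genes lie outside the axes. Points follow the diagonal, with a correlation of 0.897 across genes with a mean of at least 10 CPM.

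Set side by side, the responses of the lines were alike in direction. TGF-β1 raised 1392 genes in both lines (298 by chance) and lowered 1169 in both (269.6 by chance), while 2 rose in shMock and fell in shMTHFD2 and 2 did the reverse. Against shMock, 619 genes were lower in shMTHFD2 both with and without TGF-β1 (90.9 by chance) and 130 were higher in both (21.2 by chance). Any fixed difference between the lines would give such an overlap, so it does not show an effect of MTHFD2 itself. In size, the response in shMTHFD2 averaged 89.0% of that in shMock (SD 0.353 over 4 choices of libraries, 878 to 939 genes), with 92.6% for genes that rose and 84.6% for genes that fell. The 4 choices reuse the same shMTHFD2 libraries, so their SD does not measure the spread between replicates. The average was 87.3 to 90.8% when a shMTHFD2 library was left out. Choosing genes by their shMock response favours a smaller share in the other line, and the reverse choice was not made, so a weaker response in shMTHFD2 is not established. The mean signed changes were 1.29 and 1.15 on the log2 scale. Genes moved by TGF-β1 in shMock were often changed in the opposite direction by the knockdown. Of the 2333 genes raised by TGF-β1, 524 were lower in shMTHFD2 with TGF-β1 (192 by chance) and 44 higher (112.7 by chance), and of the 2443 lowered, 346 were higher (118 by chance) and 159 lower (201 by chance). By list, 19 of the 26 contractile genes raised by TGF-β1 were lower in the knockdown with it, 13 of 28 TGF-β/SMAD targets, 10 of 22 ATF4 targets and 3 of 14 collagens. Without TGF-β1, 15 of 28 contractile genes and 12 of 33 TGF-β/SMAD targets were lower in shMTHFD2 too. Camera called neither list for the interaction. Over the 8 fits that left out 1 library, their interaction medians ran from -0.098 to 0.029 and from 0.004 to 0.156. A difference between the lines that is present without TGF-β1 can give such counts, so they do not show a weaker activation. TGF-β1 in shMock and the knockdown with TGF-β1 share the shMock TGF-β1 libraries, so the noise of these libraries enters both with opposite sign. In 20 simulated data sets without change, at most 2 genes were called by edgeR in opposite directions, and 113 to 153 had an unadjusted p under 0.05 in both with opposite signs, against 1822 observed. These simulations hold noise alone, so their counts do not allow for genes that change in both comparisons. Over 9798 genes the fold changes correlated at -0.498 in the simulations and at -0.349 in the data. Where nothing changes, the sharing itself fixes the correlation near the simulated value, so these correlations cannot be compared. The covariance of the fold changes was -0.00846 in the simulations and -0.0526 in the data, so shared noise of the simulated size gives only part of it.

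The interaction asks whether the TGF-β1 response differs between the lines. The edgeR test called 12 genes, 5 with a more positive and 7 with a more negative response in shMTHFD2, and 4 of them passed a 2-fold minimum. Among the genes with a symbol, PTX3, a secreted pattern-recognition protein, had the largest positive difference (1.07, SE 0.12, edgeR adjusted p = 0.0014), followed by the vasodilator peptide ADM (0.97), the transcription factor OSR1 (0.95) and the GMP reductase GMPR (0.85). The kinase STK38L (-0.89), the adhesion protein AMIGO2 (-0.89), ANKHD1 (-0.77), the nuclear envelope gene SYNE1 (-0.75) and INHBA (-0.71) had more negative responses. The other 3 called IDs, ENSG00000205236, ENSG00000285238 and ENSG00000250264, carry no symbol and are named outside the rule, after their values were seen. Among the genes with a symbol only PTX3 passed the 2-fold minimum, so the rest of those 4 are such IDs. Exons of ENSG00000205236 and ENSG00000285238 overlap another gene on the same strand, so these calls are uncertain. ENSG00000205236 had no counts in shMock control and shMTHFD2 TGF-β1, against 94 in shMock TGF-β1 and 191 in shMTHFD2 control. ENSG00000285238 had none in shMTHFD2 TGF-β1, against 360 in shMTHFD2 control. PTX3 was called in each fit that left out 1 library, and the other 8 named genes lost their call in several. The losses numbered 7 without shMTHFD2 TGF-β1 1 (edgeR adjusted p = 0.0734 to 0.126), 4 without shMTHFD2 TGF-β1 2 (0.0760 to 0.0949), 8 without shMTHFD2 control 2 (0.0970 to 0.193), 8 without shMock TGF-β1 1 (0.0970 to 0.132), 7 without shMock TGF-β1 2 (0.0507 to 0.106), 2 without shMock control 1 (0.0515 to 0.0530) and 8 without shMock control 2 (0.107 to 0.238). The total was 42 without shMock control 1, 4 without shMock control 2, 3 without shMock TGF-β1 1, 185 without shMTHFD2 control 1 and 3 without shMTHFD2 control 2, and DESeq2 called 105. PTX3, AMIGO2, SYNE1 and ANKHD1 overlap a gene on the opposite strand, ANKHD1 also one on the same strand. The difference also followed GC content, with a Spearman correlation of 0.473 across genes, and with GC and length offsets 10 of the 12 were called among 18. The interferon-stimulated genes as a list were not called (median 0.13, adjusted p = 0.124), while the mitochondrially encoded mRNAs were (median -0.86, adjusted p = 1.2e-24; adjusted p = 0.664 with an estimated correlation; fry adjusted p = 0.192), with 13 lower adjusted over the list alone. Of their 13 members edgeR called 11 without shMTHFD2 control 1 and 12 without shMock control 1, and none with all libraries, where 13 had an unadjusted p under 0.05 and DESeq2 called none.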

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

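Of the tests below, both comparisons with histone mRNAs, the scaling on nuclear genes, and the requirement that a bound be passed by more than 1 SD were chosen only after the results were seen.

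The results of this part stand out because an interaction test called a difference between the TGF-β1 responses of shMTHFD2 and shMock, edgeR's for single genes and camera's for lists. For single genes, the differences on the log2 scale were 1.07 for PTX3, 0.97 for ADM, 0.95 for OSR1, 0.85 for GMPR, -0.89 for STK38L, -0.89 for AMIGO2, -0.77 for ANKHD1, -0.75 for SYNE1 and -0.71 for INHBA. Of these 9 genes, only PTX3 was called in each of the 8 fits that left out 1 library. Of the other 8, all lost their call without shMTHFD2 control 2 (edgeR adjusted p = 0.0970 to 0.193), shMock TGF-β1 1 (0.0970 to 0.132) or shMock control 2 (0.107 to 0.238), 7 without shMTHFD2 TGF-β1 1 (0.0734 to 0.126), 7 without shMock TGF-β1 2 (0.0507 to 0.106), 4 without shMTHFD2 TGF-β1 2 (0.0760 to 0.0949), and 2 without shMock control 1 (0.0515 to 0.0530). The test made 12 calls in all. In simulated data with 200 changed genes, 9.77% of its 133 calls were false, a share that need not hold for the 12 calls here.

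For gene lists, camera called 8 with the preset correlation, none of them with an estimated correlation (smallest adjusted p = 0.664) or with fry (smallest adjusted p = 0.137). The mitochondrially encoded mRNAs had a median difference of -0.86, and the glycolysis and hypoxia genes one of 0.22; both were called in each of the 8 fits that left out 1 library. NRF2 antioxidant genes had a median of 0.18, lost without shMock control 1 (adjusted p = 0.0967) and shMTHFD2 TGF-β1 1 (0.0819). For antigen presentation the median was 0.24, lost without shMock TGF-β1 1 (adjusted p = 0.0573) and with GC and length offsets (0.114). Cholesterol synthesis stood at 0.17, lost without shMock control 2 (adjusted p = 0.0517), shMock TGF-β1 2 (0.186), shMTHFD2 control 1 (0.0825) and shMTHFD2 TGF-β1 1 (0.0565). ATF4 targets stood at 0.14, lost without shMock control 1 (adjusted p = 0.18), shMock TGF-β1 1 (0.0573), shMTHFD2 control 2 (0.153) and shMTHFD2 TGF-β1 1 (0.15), and with GC and length offsets (0.656). Nuclear-encoded respiratory subunits stood at 0.12, lost without shMock control 2 (adjusted p = 0.527), shMock TGF-β1 2 (0.127), shMTHFD2 control 1 (0.0655), shMTHFD2 control 2 (0.079) and shMTHFD2 TGF-β1 1 (0.463). Ribosomal protein genes stood at 0.10, lost without shMock control 2 (adjusted p = 0.185), shMock TGF-β1 2 (0.188) and shMTHFD2 TGF-β1 1 (0.397), and with GC and length offsets (0.083).

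For the mitochondrially encoded mRNAs, camera's preset correlation called a rise in shMTHFD2 without TGF-β1 (median 0.54) and a fall with it (median -0.33), but edgeR called 10 of 13 members without TGF-β1, none of them without shMTHFD2 control 2 or shMock control 2, and none with it, and DESeq2 called none in either. Mitochondrial reads acting through library size do not account for the list's difference between the responses, since these mRNAs held only 3.51 to 7.04% of the counts. Scaling on nuclear genes alone could therefore change little, and it left the interaction median at -0.89. Uneven capture of transcripts with short or no poly(A) tails may move the histone mRNAs too, and it stays open. Their interaction median of 0.0724 (median absolute deviation 0.314 over 7 genes) became -0.23 without shMTHFD2 control 2 and 0.61 without shMTHFD2 control 1. Without TGF-β1 they stood at 0.494 (median absolute deviation 0.386), and at 0.17 without shMTHFD2 control 1. Whether these 7 genes follow such capture was not tested. A single library remains open too: over the 8 fits that left out 1 library the interaction median ran from -1.21 to -0.61 (SD 0.186), which meets the bound of -0.5 set beforehand, but by less than that SD, and passing by more than the SD was required only after the value had been seen. A change of mitochondrial transcription with the knockdown is a biological explanation that may hold and that was not tested here.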

How the results depend on the processing

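DESeq2, limma on log2 CPM, edgeR without an abundance trend, scaling on library totals, scaling on nuclear genes, and GC and length offsets were chosen after the data had been seen. The other settings were fixed before. The counts of changed genes for the knockdown with and without TGF-β1 and for TGF-β1 in each line stayed within 1.5 times under every setting except the 2-fold minimum, with 130, 111, 1016 and 779 genes, and leaving out single libraries. There the counts ran from 845 to 1820 for the knockdown with TGF-β1 and from 638 to 1674 without it, while TGF-β1 gave 3297 to 4791 in shMock and 2373 to 3344 in shMTHFD2. DESeq2 called 1768, 1544, 4543 and 3056. The interaction count of 12 was the least stable: it was 4 with a 2-fold minimum, 321 without a filter on low counts, 36 at a mean CPM of at least 5, 5 with quantile normalisation, 105 with DESeq2, and 3 to 185 when 1 library was left out. A filter changes both the adjustment and the genes that enter the fit. The cause of these differences was not tested. The size of the response in shMTHFD2, 89.0% of that in shMock, was 92.7% for genes at a log2 difference of at least 2, 90.5% with a pseudocount of 0.1, 91.0% with GC and length offsets, and 87.3 to 90.8% when 1 shMTHFD2 library was left out. Replicate numbers did not pair the samples (correlations of replicate differences -0.0203 to 0.0687), and with the replicate block the counts were 1734, 1530, 4753, 3194 and 13. In the 431 values of named genes, the only reversal was RPL3 for TGF-β1 in shMTHFD2, at -0.25 with quantile normalisation against 0.00 with edgeR, which did not call it; the cause was not tested. Among these values 18 lost their call with library totals, 26 with quantile normalisation, 20 with GC and length offsets and 7 with DESeq2, and 23 to 55 when 1 library was left out. Depth limits the weakest genes, since 3 counts stand at 0.135 to 0.165 CPM. In simulation, with 2 libraries per group, 59.7% of 1.5-fold changes were recovered.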

Other observations

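Of the tests below, the GC trend with the offsets that remove it, and the reading of the interferon-stimulated genes as a difference between the lines, were chosen only after the results were seen.

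Of 27 genes of glycolysis and the hypoxia response, 14 fell in the knockdown without TGF-β1 and 13 did not pass (18 lower adjusted over the list alone), among them ADM (-0.85, 146 ± 26.7 against 263 ± 3.78 CPM) and the glycolytic enzyme PGAM1 (-0.69, 212 ± 3.59 against 342 ± 20.1 CPM; adjusted p = 1.4e-09 for the list; adjusted p = 0.114 with an estimated correlation). The count was 9 without shMTHFD2 control 1, 5 without shMTHFD2 control 2 and 7 without shMock control 2. With TGF-β1, 4 of the 27 fell and 1 rose (5 and 1 adjusted over the list alone), with the carbonic anhydrase CA12 at -0.92, PGAM1 at -0.52 and the enolase ENO2 at 0.51, and the list was not called (median -0.05, adjusted p = 0.173). There 2 fell without shMTHFD2 TGF-β1 1 and 2 without shMTHFD2 TGF-β1 2, and the median turned positive with library totals (0.04) and quantile normalisation (0.03). Of 24 genes of cholesterol synthesis and uptake, 9 fell without TGF-β1 and 15 did not pass (15 lower adjusted over the list alone; adjusted p = 1.6e-07; adjusted p = 0.0973 with an estimated correlation), and 3 fell without shMTHFD2 control 2 and 5 without shMock control 2. With TGF-β1, 7 of the cholesterol genes fell (9 lower and 1 higher adjusted over the list alone), with the epoxidase SQLE at -0.52. That list's call (adjusted p = 0.0121; adjusted p = 0.28 with an estimated correlation) was lost without shMock TGF-β1 1 (adjusted p = 0.0691), where 4 fell, and 2 fell without shMTHFD2 TGF-β1 1 and 4 without shMTHFD2 TGF-β1 2.

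Enzymes that fold and crosslink collagen followed TGF-β1 upward in shMock, where 14 of 21 rose and 3 fell (14 and 3 adjusted over the list alone), with the lysyl hydroxylase PLOD2 at 1.95 (480 ± 30.4 against 125 ± 10.2 CPM; adjusted p = 9.5e-08 for the list; adjusted p = 0.163 with an estimated correlation). Of the lower members 1 was left without shMock TGF-β1 1 and 1 without shMock control 1, and no member fell in edgeR without shMock TGF-β1 2 or shMock control 2. Without TGF-β1, 9 of the 21 were lower in the knockdown (13 lower adjusted over the list alone), with P3H4 at -0.63 and the lysyl oxidase LOX at -0.59 (285 ± 11.2 against 430 ± 2.91 CPM; adjusted p = 1.5e-05 for the list; adjusted p = 0.168 with an estimated correlation). That count was 2 without shMTHFD2 control 2, 4 without shMock control 1 and 3 without shMock control 2. With TGF-β1, 5 of the 21 were lower (5 adjusted over the list alone), with LOX at -0.56, and the list's call (adjusted p = 0.00647; adjusted p = 0.395 with an estimated correlation) was lost without shMock TGF-β1 1 (adjusted p = 0.0556). That count was 3 without shMTHFD2 TGF-β1 1, 3 without shMTHFD2 TGF-β1 2, 2 without shMock TGF-β1 1 and 10 with GC and length offsets. The p53 targets moved both ways without TGF-β1. Of 25 genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone), with the stress gene SESN1 at 0.65, the RNA-binding ZMAT3 at 0.64 and the cyclin CCNG1 at -0.75, and the list was not called (adjusted p = 0.198). The higher count was 3 without shMTHFD2 control 2 and 3 without shMock control 2. LOX and SESN1 overlap a gene on the opposite strand.

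In the knockdown with TGF-β1 the median log2 fold change was -0.10 in the fifth of genes with the lowest GC content and 0.16 in the fifth with the highest, and for TGF-β1 in shMock these medians were 0.12 and -0.22. The Spearman correlation with GC content was 0.329 and -0.285 in these comparisons and 0.473 for the interaction, against -0.143 for the knockdown without TGF-β1 and 0.0232 for TGF-β1 in shMTHFD2. With offsets that take the trend off, 16 of 16 list calls were kept for the knockdown with TGF-β1, 19 of 20 without it and 5 of 8 for the interaction. The genes raised by TGF-β1 and lowered by the knockdown numbered 524 with the offsets too (198 by chance), and those lowered and then raised numbered 282 (96.9 by chance).

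Interferon-stimulated genes were lower in shMTHFD2 with and without TGF-β1. No single library carries this, as at least 28 of the 40 genes were called lower in either comparison whichever library was left out. GC content and length do not carry it either: after the median of the 200 genes nearest in GC and length was taken off, the list stood at -0.79 with TGF-β1 and -0.93 without it. What stays open is whether the loss of MTHFD2 or another difference between the lines, such as an interferon response in the shMock cells, may be the source. The interaction median of 0.13 is small beside the knockdown medians of -0.84 and -0.98, and without a further hairpin, a rescue or an untransduced line these cannot be told apart.

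Of the tested genes, 9 had no counts in both libraries of 1 group and at least 1 CPM in both libraries of another. They are IGF1, WNT11, INO80B-WBP1, TBC1D3D, the MKKS ID and 4 IDs without a symbol, and TBC1D3D was named after its values were seen. A candidate explanation is that reads of overlapping genes were shared out unevenly between libraries. Of the 9, 66.7% (6 genes) have exons overlapping another gene on the same strand, against 18.8% of the tested genes (Fisher's exact test, two-sided p = 0.00219), as that explanation needs. IGF1, WNT11 and TBC1D3D have no such overlap, and TBC1D3D has close paralogs.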
